A study of Homo sapiens with 21 samples.

How the data were processed

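RNA was measured in H1 human embryonic stem cells at 0, 3, 6, 12, 24, 48 and 72 h of neural induction by dual-SMAD inhibition, with 3 libraries per time point. Per the labels, the cells were kept in mTeSR1 on matrigel, RNA was taken with RNeasy mini columns, and libraries were made with the TruSeq Stranded Total RNA kit. The label for the source of the material names neural progenitor cells for every library, including those of 0 h, and the time points were taken from the labels of the hours. The submitters' processing notes name Trimmomatic 0.3.2, TopHat2 2.1.1 with the hg19 genome, SAMtools 1.3.1, Picard, featureCounts 1.5.0-p3, Cufflinks and FastQC 0.3.2. They do not give the strand setting, the annotation or the handling of reads with several positions. The ChIP-seq, ATAC-seq and reporter assays of the same study were not analysed here.

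The values are raw read counts per gene, deposited by the authors as a single table of 35900 entries. Of these, 824 (2.30%) had no values and were left out. Another 30 entries carried names that spreadsheet programs turn into dates and were kept apart, since 1 such name can stand for several genes. Names that appeared in several entries (1991 of them) were added up, which left 31517 genes. The 106 values of at least 1050000 are given to 3 digits in the table, which bears on the most abundant genes alone. Several genes that cells commonly use, such as TPI1, PGK1, NSDHL and EBP, are listed at 0 in all libraries, so a 0 in the table is not evidence that a gene was silent. Positions were taken from the GRCh37 annotation by gene symbol, which matched 26829 names. Of 21719 genes tested, 19212 (88.5%) had a gene type. The library totals were 73689263 to 314729551 counts.

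Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the time points as groups, library sizes were scaled with TMM, and a quasi-likelihood model with robust estimation was fitted to all 21 libraries with time point as a factor, which left 14 residual degrees of freedom. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each comparison. A gene was called when its adjusted p was under 0.05. The comparisons were an F test over the whole course, 6 contrasts with 0 h and 5 contrasts of successive time points. A gene was called transiently higher or lower when its level at 1 of the 5 middle time points lay above or below both 0 and 72 h, taking the larger of both p-values, multiplied by 5 for the choice of time point and adjusted over all genes. An exact test of 3 libraries against 3 on a single gene cannot give a p below 0.1. The model avoids this limit by pooling the spread across genes, and it assumes that libraries are independent. Levels in CPM use the scaled library sizes. A gene with no counts in a group was given a lower bound against a floor of 3 counts over the group, and a gene with 1 to 3 counts a ratio with an exact 95% interval from the counts.

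Before the data were examined, 34 gene lists were fixed, of which 33 could be tested, as no member of the list of mitochondrially encoded genes is in the table. Each was tested at the 6 later time points with camera of limma 3.58.1 (198 tests adjusted together), with a preset correlation of 0.01 between genes and a prior count of 2, and again with the correlation estimated from the data. Camera compares a list with all other genes. The comparisons, the alternatives and the rule for naming genes were set at the same point. Outside the lists, named genes come from the largest changes (10 in each direction at 3, 24 and 72 h, 5 at 6, 12 and 48 h) among genes with adjusted p under 0.05, no overlap of libraries between the groups, and a mean of at least 5 CPM at the higher time point. Within lists they are the up to 4 members per list and time point with the largest change and at least 1 CPM, and any other member given with its value. Transient genes are the 10 in each direction with the largest value of the smaller log2 change. XIST, Y-linked genes and genes without a clear description were not named.

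The alternatives were DESeq2 size factors, DESeq2 1.42.0 in place of edgeR, no filter on low counts, a stricter filter (at least 5 CPM in at least 3 libraries), the replicate number as a block, a fit to only the libraries compared, no robust estimation, leaving out the 10 most abundant genes and mitochondrial genes, and leaving out each library in turn. For lists, a prior count of 0.5 was also tried. After seeing the data, 4 settings were added. They are the class of mitochondrial rRNA share (above or below 5%) as a term, the 12 libraries of low share alone, the 9 of high share alone, and the highest entry of a repeated name in place of the sum. The lists of genes for WNT ligands, Frizzled receptors, R-spondins, fatty acid synthesis and LXR targets, were added after seeing the data as well (30 tests adjusted together). The whole procedure was tested on simulated data with known changes, in which 185 of 200 changed genes were found over the course, 13 of 19896 unchanged genes were called, and 0 of 50 random lists passed. The changed genes were drawn from those with at least 1 CPM at 0 h. Genes were simulated independently and without an effect of rRNA class. Only 200 genes were changed, of 20096 tested there, with as many raised as lowered, whereas 20432 of 21719 real genes were called over the course. These rates therefore do not cover weaker genes, lists whose members vary together, that class, or scaling where most genes change. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.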

Results

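H1 cells, an established human embryonic stem cell line, were followed through the first 72 h of neural induction. The induction used dual-SMAD inhibition, in which inhibitors block BMP signalling and Activin/Nodal/TGF-beta signalling so that pluripotent cells turn towards neural progenitors. Total RNA was sequenced at 7 time points, 0, 3, 6, 12, 24, 48 and 72 h, with 3 libraries each and 21 libraries in all. The values are counts per gene for 31517 gene names, of which 21719 passed the filter on low counts. The 0 h libraries held 151348140, 140422005 and 111431433 counts and the 3 h libraries 99958313, 104168672 and 110369068. The totals were 145024203, 234490337 and 161742687 at 6 h and 73689263, 110320360 and 92922178 at 12 h. They were 131581666, 127898216 and 138126188 at 24 h, 314729551, 112390183 and 121355546 at 48 h, and 155708479, 132480170 and 136882006 at 72 h. Levels are given as the mean counts-per-million value (CPM) ± SD over 3 libraries, and changes as log2 fold changes ± SE. The labels do not say that the 3 libraries of a time point came from separate cultures, so the p-values measure only the spread between libraries.

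The libraries fell into a pair of classes by their share of mitochondrial rRNA, the transcripts RNR1 and RNR2 that a total RNA library keeps or loses with its rRNA depletion. The share was 0.0293% to 0.183% in 12 libraries and 9.62% to 19.1% in 9. All libraries of 3, 24 and 72 h had a low share and all libraries of 12 and 48 h a high one. At 0 h replicate 3 alone had a high share, and at 6 h replicates 2 and 3 did. The labels name no library batch, so the numbers of genes called are given also with the class as a term and, for contrasts whose time points both have such libraries, within a class. The steps from 12 to 24 h, from 24 to 48 h and from 48 to 72 h have no library of the same class on both sides, and there the class as a term rests on the 0 and 6 h libraries. Between replicates of a time point the correlation of log2 CPM was 0.987 to 0.997 across genes, and genes are not independent replicates.

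**Figure D1:**
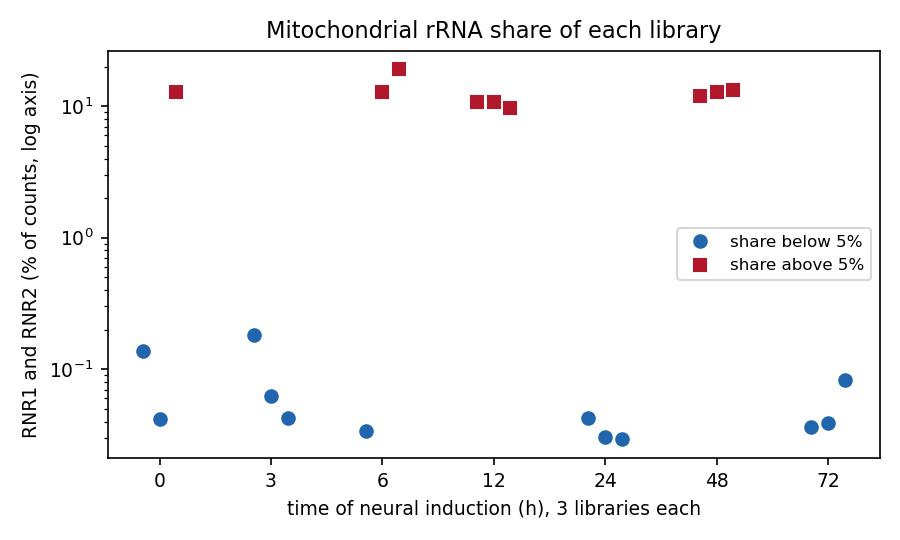
Share of counts on the mitochondrial rRNA genes RNR1 and RNR2 in each of the 21 libraries (log axis), by time point. The 12 libraries of low share lie between 0.0293% and 0.183%, and the 9 of high share between 9.62% and 19.1%.

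The test over the whole course asked which genes differed between any time points. Of 21719 genes, 20432 did, and 20327 with the class as a term. Among the 13704 genes whose mean level differed at least 2-fold between their highest and lowest time point, 3806 were highest at 3 h and 3075 at 72 h, while 2574 were lowest at 0 h and 3463 at 72 h. On log2 CPM, the first principal component held 46.2% of the variance and the second 15.7%. Data were simulated at this depth, with 50 genes of at least 1 CPM at 0 h per kind of change. There the comparison of 24 h with 0 h found 80% of genes raised 1.5-fold and 98% of genes lowered 2-fold. It called 2 of 19996 unchanged genes. Only 200 of 20096 genes were changed there, so these rates do not cover scaling where most genes change. Of 33 gene lists tested at 6 time points, 67 of 198 tests passed with a preset correlation between genes and 24 of these with an estimated correlation. The first number counts lists that moved apart from other genes if members vary almost independently. The second holds also where they vary together.

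**Figure D2:**
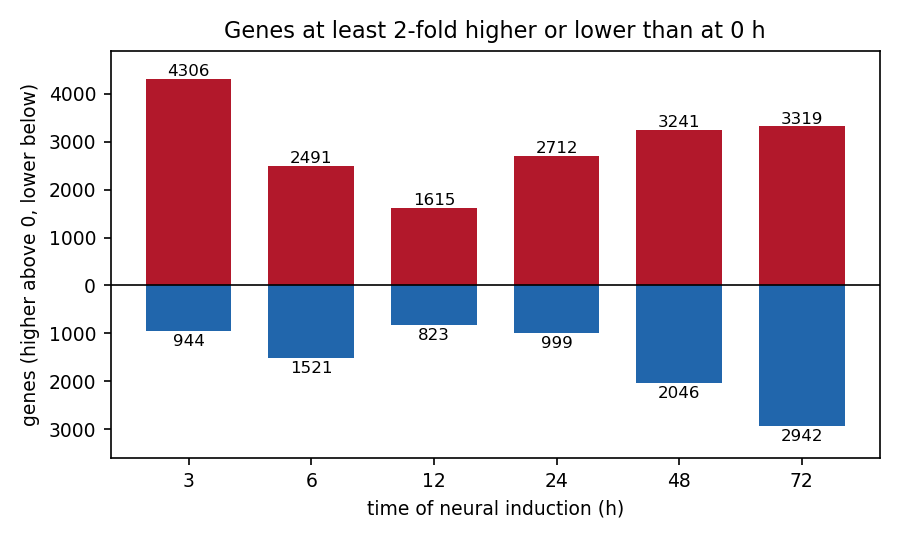
Genes at least 2-fold higher (above 0) or lower (below 0) than at 0 h with adjusted p under 0.05, at each later time point, of 21719 genes tested. Over all genes tested, the most higher genes were at 3 h (4306) and the most lower at 72 h (2942), while among genes with at least 1 CPM the most higher genes were at 72 h (1966, against 1470 at 3 h).

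At 3 h, the comparison with 0 h asked which genes responded earliest. Higher genes numbered 7737 and lower genes 6358, of which 4306 and 944 changed at least 2-fold. Among the 14876 genes with at least 1 CPM at either time point, 1470 were at least 2-fold higher and 755 lower. Counted the same way, 1769 were higher at 48 h and 1966 at 72 h, so 3 h had the most higher genes only with weakly expressed genes included. With the rRNA class as a term 7910 were higher and 6513 lower, within the low class (3 libraries against 2) 8654 and 8172, and no gene of both sets went opposite ways. Immediate-early genes, which cells transcribe within minutes of a stimulus, all rose (15 of 15 measured; adjusted p = 1.1e-08, and 0.0414 with an estimated correlation). EGR1, a zinc finger factor of this class (chromosome 5, 137801168 to 137804992), went from 1.52 ± 0.466 to 82.9 ± 15.3 CPM, a change of 5.79 ± 0.32 on the log2 scale. The AP-1 genes FOS (2.58 ± 0.11) and JUN (3.55 ± 0.22) rose with it. Targets of YAP and TEAD, which respond to cell shape and adhesion, rose as a list (7 rose and 2 fell of 9; adjusted p = 0.0199, and 0.165 with an estimated correlation), among them CTGF (4.82 ± 0.31, to 368 ± 11.97 CPM) and AMOTL2 (2.87 ± 0.10). The chemokine gene IL8 had 6898 counts at 3 h and none at 0 h, at least 2399-fold higher against a floor of 3 counts over the group, and NPPB, which encodes a natriuretic peptide, was at least 1095-fold higher on the same floor. TXNIP, an inhibitor of thioredoxin and glucose uptake, rose by 5.50 ± 0.14 and the muscle actin gene ACTA1 by 4.75 ± 0.14. TXNIP has repeated entries in the table, which were added up, so its level is uncertain.

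Pluripotency factors fell as a list at 3 h (1 rose, 12 fell and 2 did not pass of 15; adjusted p = 4.3e-04, and 0.0435 with an estimated correlation), by small amounts. The largest falls were in VRTN, a DNA-binding factor (-0.92 ± 0.07), the NODAL coreceptor gene TDGF1 (-0.90 ± 0.09) and the DNA methyltransferase gene DNMT3B (-0.78 ± 0.06), and NANOG fell by less (-0.60 ± 0.09). Factors shared by pluripotent and neural progenitor cells fell too (1 rose and 6 fell of 8; adjusted p = 0.00538, and 0.0435 with an estimated correlation). OTX2, a forebrain and midbrain factor (chromosome 14, 57266623 to 57283411), went from 81.2 ± 5.17 to 21.7 ± 0.638 CPM, a change of -1.90 ± 0.10. SOX3 was the 1 that rose (0.89 ± 0.12). FEZF1, a forebrain factor, changed by -3.56 ± 0.09, and its antisense neighbour FEZF1-AS1, from which its reads may not be told apart, by -3.07 ± 0.11. All 10 measured posterior neural factors rose (adjusted p = 7.9e-04, and 0.0225 with an estimated correlation), 8 of them from under 1 CPM at 0 h. EGR2, a hindbrain factor that is also an immediate-early gene, was among them (3.69 ± 0.17). GBX2, a hindbrain factor (chromosome 2, 237073879 to 237077029), went from 0.209 ± 0.0274 to 6.17 ± 0.0750 CPM. Large falls outside the lists were in the calcium channel gene TRPC4 (-3.28 ± 0.08) and the semaphorin gene SEMA6D (-3.22 ± 0.12). The largest adjusted p among genes named in this paragraph was that of NANOG (4.8e-06).

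Stress and metabolic lists also moved at 3 h. Genes of the integrated stress response rose (9 rose, 1 fell and 4 did not pass of 14; adjusted p = 0.0121, and 0.165 with an estimated correlation), with DDIT3, a factor induced by unfolded protein, at 3.10 ± 0.10 and the mTOR inhibitor gene DDIT4 at 2.47 ± 0.18. Hypoxia response genes rose (8 of 10; adjusted p = 0.00471, and 0.0657 with an estimated correlation), led by NDRG1 (3.16 ± 0.15). Glycolysis genes rose (9 rose and 1 fell of 14; adjusted p = 0.0351, and 0.481 with an estimated correlation), among them the lactate transporter gene SLC16A3 (4.08 ± 0.12) and LDHA (1.44 ± 0.22), but that call ended without 0 h replicate 3 (adjusted p = 0.0523) and with the rRNA class as a term (0.0615). Cholesterol synthesis genes fell (19 of 21; adjusted p = 5.6e-07, and 0.129 with an estimated correlation), the most in the mevalonate kinase gene MVK (-1.52 ± 0.08). S phase genes fell (1 rose and 12 fell of 20; adjusted p = 0.00427, and 0.405 with an estimated correlation), with cyclin genes CCNE1 at -1.28 ± 0.08 and CCNE2, the 1 that rose, at 1.19 ± 0.11. Of 20 G2/M genes 15 fell (adjusted p = 3.9e-04, and 0.195 with an estimated correlation), with the checkpoint kinase gene BUB1 at -1.25 ± 0.08. Replication-dependent histone genes fell (6 of 12; adjusted p = 0.0392, and 0.542 with an estimated correlation), and that call ended without 0 h replicate 1 (0.0800) or without 3 h replicate 1 (0.0622). Histone genes resemble each other in sequence, so single members are uncertain. Genes of higher level at 0 h had a median change of -0.25 at 3 h. The medians were -0.47 for G2/M, -0.44 for S phase and -0.30 for histone genes. They were -0.84 for cholesterol synthesis genes, -0.62 for pluripotency factors and -0.94 for the shared factors. No comparison with lists of like expression was run for these falls, so the part of that general fall in them was not tested. Adjusted over the list alone, the numbers of members higher and lower were the same for all 12 lists called at 3 h.

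The comparison of 6 h with 0 h asked whether targets of the blocked pathways had fallen. Higher genes numbered 6430 and lower genes 5696, of which 2491 and 1521 changed at least 2-fold. The numbers were 6161 and 5563 with the class as a term, within the low class (1 library against 2) 5760 and 6398, and within the high class (2 against 1) 2955 and 3116, with no gene of both sets going opposite ways. SMAD7, the inhibitory SMAD that TGF-beta and Nodal signals induce (chromosome 18, 46446223 to 46477335), went from 24.5 ± 0.687 to 1.83 ± 0.0881 CPM, a change of -3.74 ± 0.09 (adjusted p = 3.1e-18). LEFTY1, a Nodal target and antagonist, changed by -2.71 ± 0.24 and PMEPA1 by -2.49 ± 0.10. Of 11 Activin/Nodal/TGF-beta targets 4 rose, 6 fell and 1 did not pass, and the list did not pass (adjusted p = 0.295, and 0.419 with an estimated correlation). ID1, a dominant-negative helix-loop-helix gene and BMP target (chromosome 20, 30193086 to 30194318), went from 47.0 ± 5.87 to 3.58 ± 0.183 CPM, a change of -3.71 ± 0.12, and ID3 changed by -1.73 ± 0.10. BMP targets did not pass as a list (2 rose, 6 fell and 3 did not pass of 11; adjusted p = 0.0713, and 0.475 with an estimated correlation). Notch targets fell (1 rose and 6 fell of 10; adjusted p = 0.0103, and 0.111 with an estimated correlation), with HES1, a repressor of neuronal differentiation, at -1.65 ± 0.08 and HES4, the 1 that rose, at 3.57 ± 0.36.

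NANOG, a core pluripotency factor (chromosome 12, 7940390 to 7951742), fell from 138 ± 6.61 to 50.3 ± 2.29 CPM by 6 h (-1.45 ± 0.09), in a list that fell (1 rose, 10 fell and 4 did not pass of 15; adjusted p = 0.00284, and 0.0710 with an estimated correlation). The member that rose was DPPA2, in a call that ended with DESeq2 size factors (adjusted p = 0.0708), DESeq2 (0.0757) and no filter (0.105). It also ended without 0 h replicate 2 (0.142) or 3 (0.226), among other libraries. OTX2 was lowest at this time point (-3.09 ± 0.11), as were FEZF1 (-4.54 ± 0.09) and CRB2, a gene of epithelial polarity (-4.00 ± 0.08). Immediate-early genes remained higher (13 of 15; adjusted p = 1.4e-05, and 0.0861 with an estimated correlation) with EGR1 at 4.34 ± 0.30, and so did YAP/TEAD targets (7 of 9; adjusted p = 8.6e-04, and 0.0509 with an estimated correlation) and posterior neural factors (6 rose and 1 fell of 10; adjusted p = 0.0122, and 0.0607 with an estimated correlation). KLF5, a factor of naive pluripotency and epithelia, rose by 5.09 ± 0.15. Cholesterol synthesis genes fell (20 of 21; adjusted p = 7.2e-09, and 0.0781 with an estimated correlation). The hypoxia list rose (7 rose and 1 fell of 10; adjusted p = 0.00764, and 0.0772 with an estimated correlation). All 6 metallothionein genes, which bind zinc and copper and share sequence, rose (adjusted p = 0.0127, and 0.403 with an estimated correlation). Glycolysis genes (7 rose and 1 fell of 14; adjusted p = 0.0425, and 0.4996 with an estimated correlation) and stress response genes (7 of 14; adjusted p = 0.0425, and 0.247 with an estimated correlation) rose too. The glycolysis call ended without 0 h replicate 3 (0.0633), 6 h replicate 1 (0.0963), 12 h replicate 3 (0.0511) or 48 h replicate 3 (0.0507), and within the high class (0.113). The stress call ended without 0 h replicate 3 (0.0629) or 6 h replicate 1 (0.0642), and within the high class (0.0683). Adjusted over the list alone, member counts were the same for all 10 lists called.

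At 12 h the comparison with 0 h asked how far the pluripotency programme had fallen before most neural genes rose. Higher genes numbered 4719 and lower genes 4798, of which 1615 and 823 changed at least 2-fold. Replicate 3 at 12 h lay apart from the other 2 libraries, and without it 1428 genes were at least 2-fold lower. With the class as a term 4538 were higher and 4331 lower, and within the high class (3 libraries against 1) 2424 and 1859, with none opposite in both sets. Pluripotency factors fell (0 rose, 14 fell and 1 did not pass of 15; adjusted p = 2.6e-06, and 0.0175 with an estimated correlation), with NANOG at -2.95 ± 0.09 and PRDM14, a repressor of differentiation, at -1.66 ± 0.07. Activin/Nodal/TGF-beta targets fell as a list (1 rose and 9 fell of 11; adjusted p = 8.4e-05, and 0.0175 with an estimated correlation), with SMAD7 at -3.97 ± 0.09. YAP/TEAD targets rose (7 of 9; adjusted p = 1.4e-05, and 0.0225 with an estimated correlation), with ANKRD1, a muscle ankyrin repeat gene, at 7.99 ± 0.25. TAGLN, a smooth muscle gene on the fibroblast list, reached 1039.8 ± 232 CPM (5.08 ± 0.14). Endoderm markers rose (7 of 8; adjusted p = 3.6e-04, and 0.0204 with an estimated correlation) from low levels, with the chemokine receptor gene CXCR4 at 3.03 ± 0.349 CPM (2.27 ± 0.13) and FOXA2 at 2.72 ± 0.0338 CPM (1.86 ± 0.20). VGF, a gene of secreted neuropeptides (chromosome 7, 100805790 to 100808850), rose from 2.35 ± 0.0823 to 211 ± 23.7 CPM (6.49 ± 0.13), and ANXA1, an annexin gene, rose by 7.38 ± 0.25. NPPB was at least 6921-fold higher on the floor of 3 counts.

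Anterior neural factors were lower at 12 h (1 rose, 5 fell and 7 did not pass of 13, 1 and 6 adjusted over the list alone; adjusted p = 0.0409, and 0.129 with an estimated correlation), with HESX1, a pituitary and forebrain repressor, at -2.80 ± 0.14, while LHX5 was above 0 h (1.18 ± 0.15). That call ended without 0 h replicate 2 (0.0575) or 12 h replicate 3 (0.153) and within the high class (0.0683). Posterior neural factors were higher (7 of 10; adjusted p = 7.9e-04, and 0.0225 with an estimated correlation). Retinoic acid response genes rose (6 rose and 1 fell of 8, 6 and 2 adjusted over the list alone; adjusted p = 0.0162, and 0.204 with an estimated correlation), with the receptor gene RARB at 2.14 ± 0.12. The call ended with the class as a term (0.0504) and within the high class (0.127). Cholesterol synthesis genes fell (20 of 21, and 21 adjusted over the list alone; adjusted p = 3.2e-10, and 0.0637 with an estimated correlation). Immediate-early genes (10 rose and 2 fell of 15; adjusted p = 0.00342, and 0.250 with an estimated correlation) and stress response genes (8 of 14; adjusted p = 0.00153, and 0.0781 with an estimated correlation) were higher, with DDIT3 at 2.41 ± 0.10. S phase genes were lower (1 rose and 11 fell of 20, 1 and 12 adjusted over the list alone; adjusted p = 0.00110, and 0.314 with an estimated correlation), but not within the high class (0.0530). Metallothionein genes rose (5 of 6; adjusted p = 0.0486, and 0.481 with an estimated correlation) in a call at the margin. It ended with DESeq2 size factors (0.0518), with the replicate number as a block (0.0550), with the class as a term (0.0582), within the high class (0.0683), and without any 1 of 9 libraries. These were 0 h replicates 1 (0.0649) and 3 (0.0699), 3 h replicate 1 (0.0514), 6 h replicate 1 (0.0513), 12 h replicates 1 (0.0620) and 2 (0.0978), 24 h replicate 3 (0.0506), and 48 h replicates 2 (0.0518) and 3 (0.0533). For the other lists called at 12 h the counts adjusted over the list alone were the same.

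By 24 h, the comparison with 0 h showed the rise of the earliest neural genes. Higher genes numbered 6586 and lower genes 5105, of which 2712 and 999 changed at least 2-fold. The numbers were 6704 and 5150 with the class as a term, and 7661 and 6643 within the low class (3 libraries against 2), where 1 gene called in both sets went the opposite way. SOX1, the earliest factor specific to the neural plate (chromosome 13, 112721463 to 112726020), went from 0.104 ± 0.0124 to 6.11 ± 0.709 CPM, a change of 5.88 ± 0.17 (adjusted p = 1.3e-16). The Notch effector gene HES5 rose by 4.88 ± 0.30 and MEIS2, a TALE homeobox gene, by 3.35 ± 0.25. PAX6, a later neural factor, did not pass (0.44 ± 0.19, adjusted p = 0.0574), though it passed without 0 h replicate 1 (0.0167), 12 h replicate 1 (0.0393), 24 h replicate 1 (0.0373) or 24 h replicate 2 (0.0491). The pan-neural list rose (10 rose, 3 fell and 5 did not pass of 18, 11 and 3 adjusted over the list alone; adjusted p = 0.0391, and 0.216 with an estimated correlation), and missed the threshold with the class as a term (0.0509) and within the low class (0.0517). Posterior neural factors remained higher (7 of 10; adjusted p = 0.00232, and 0.0359 with an estimated correlation), with IRX3 at 3.19 ± 0.14. IGFBP5, an IGF-binding protein gene, rose by 5.88 ± 0.11 to 91.3 ± 4.48 CPM, TXNIP by 6.30 ± 0.14, and CTCFL, a testis paralogue of CTCF, by 4.56 ± 0.15. Falls outside the lists included TIMP4, a metalloproteinase inhibitor gene (-4.42 ± 0.13), and METTL7A, a methyltransferase gene (-3.28 ± 0.11). RNR1, a mitochondrial rRNA, changed by -7.94 ± 2.42, but by -1.63 with the class as a term, where it did not pass (adjusted p = 0.168), by -1.89 within the low class (0.117) and by -1.91 without 0 h replicate 3 (0.322).

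FGF/ERK and Activin/Nodal/TGF-beta targets were lower at 24 h. Of 14 FGF/ERK feedback and target genes, 3 rose and 10 fell (adjusted p = 8.6e-04, and 0.0853 with an estimated correlation), with the phosphatase gene DUSP6 (chromosome 12, 89741012 to 89746278) at -2.94 ± 0.12, the Sprouty gene SPRY4 at -2.62 ± 0.13, and PHLDA1, a member that rose, at 2.21 ± 0.09. Activin/Nodal/TGF-beta targets fell (2 rose and 9 fell of 11; adjusted p = 1.8e-04, and 0.0175 with an estimated correlation), with SMAD7 at 0.986 ± 0.109 CPM (-4.63 ± 0.09). NANOG stood at -2.87 ± 0.09, while TDGF1 was above 0 h (0.36 ± 0.09, 804 ± 12.8 CPM), in a pluripotency list that fell (2 rose, 8 fell and 5 did not pass of 15; adjusted p = 0.00780, and 0.101 with an estimated correlation). Cholesterol synthesis genes fell (18 of 21; adjusted p = 1.7e-13, and 0.0388 with an estimated correlation). INSIG1, the sterol-sensing retention protein gene (chromosome 7, 155089486 to 155101945), changed by -2.51 ± 0.12 and HMGCS1, the synthase that opens the mevalonate pathway, by -2.42 ± 0.19. Retinoic acid response genes were higher (6 rose and 2 fell of 8; adjusted p = 0.0149, and 0.204 with an estimated correlation), with the carrier gene CRABP2 at 2.11 ± 0.11. Targets of p53 rose (11 rose and 1 fell of 15, 12 and 1 adjusted over the list alone; adjusted p = 0.00284, and 0.314 with an estimated correlation), with BTG2, an antiproliferative gene, at 2.05 ± 0.10. S phase genes fell (11 of 20; adjusted p = 4.3e-04, and 0.259 with an estimated correlation), with the licensing factor gene CDC6 at -1.15 ± 0.07. All 6 metallothionein genes fell (adjusted p = 5.7e-04, and 0.204 with an estimated correlation). Hypoxia genes were higher (6 rose and 2 fell of 10, 7 and 2 adjusted over the list alone; adjusted p = 0.0391, and 0.165 with an estimated correlation), a call that ended with the class as a term (0.0536). Counts adjusted over the list alone were the same for the other lists called at 24 h.

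At 48 h, the comparison with 0 h showed most neural progenitor genes raised. Higher genes numbered 7294 and lower genes 6251, of which 3241 and 2046 changed at least 2-fold. They numbered 6598 and 5726 with the class as a term, and within the high class (3 libraries against 1) 4367 and 3720, with none opposite. The pan-neural list rose (17 rose and 1 fell of 18; adjusted p = 9.6e-07, and 0.0175 with an estimated correlation). SOX1 stood at 37.5 ± 3.32 CPM (8.50 ± 0.17), MEIS2 at 6.67 ± 0.25, SOX21, a repressor in neural progenitors, at 4.35 ± 0.09, and PAX6 at 2.01 ± 0.18. Anterior neural factors rose (8 rose, 1 fell and 4 did not pass of 13, 10 and 1 adjusted over the list alone; adjusted p = 0.00527, and 0.0502 with an estimated correlation). LHX5, a forebrain LIM homeobox gene (chromosome 12, 113899838 to 113910085), went from 0.441 ± 0.104 to 114 ± 3.48 CPM (adjusted p = 9.4e-20), and OTX2 stood above its 0 h level, at 474 ± 53.96 CPM (2.55 ± 0.10). Retinoic acid response genes rose (6 rose and 1 fell of 8; adjusted p = 0.00141, and 0.0861 with an estimated correlation), with CYP26A1, which degrades retinoic acid (chromosome 10, 94833232 to 94837642), at 372 ± 25.4 CPM against 6.11 ± 0.717 (5.93 ± 0.13). GREB1L, a cofactor gene of retinoic acid signalling, rose by 7.42 ± 0.16. The WNT ligand gene WNT10A had 3839 counts against 1 at 0 h, a ratio of 2987 with an exact 95% counting interval of 536 to 118022, and WNT10B rose by 8.19 ± 0.19.

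NANOG (-5.49 ± 0.11) fell far at 48 h, in a pluripotency list that fell (1 rose and 13 fell of 15, adjusted p = 3.5e-05, and 0.0237 with an estimated correlation). FOXD3, a factor of pluripotent and neural crest cells, fell far too (-5.26 ± 0.16). It is on the neural crest list, which did not pass at 48 h (adjusted p = 0.971). POU5F1, which is spread over several entries of the table and is therefore uncertain, changed by -1.53 ± 0.13. The ETS factor genes ETV5 (-4.75 ± 0.10) and ETV4 (-4.49 ± 0.11) and DUSP6 (-4.92 ± 0.13) fell within the FGF/ERK list (2 rose and 11 fell of 14; adjusted p = 3.0e-04, and 0.0657 with an estimated correlation). Activin/Nodal/TGF-beta targets fell (3 rose and 7 fell of 11; adjusted p = 0.00361, and 0.0388 with an estimated correlation), with GDF3, a TGF-beta family ligand gene, at -5.77 ± 0.18. The cholesterol list fell (18 of 21; adjusted p = 3.3e-12, and 0.0435 with an estimated correlation) and so did the stress response list (2 rose and 11 fell of 14; adjusted p = 0.00141, and 0.0772 with an estimated correlation), with CHAC1, which degrades glutathione, at -2.47 ± 0.12. S phase genes fell (15 of 20, 16 adjusted over the list alone; adjusted p = 6.1e-05, and 0.204 with an estimated correlation). Histone genes fell (10 of 12, with 11 lower and 1 higher adjusted over the list alone; adjusted p = 0.00764, and 0.479 with an estimated correlation), though not within the high class (0.0705). Metallothionein genes fell (5 of 6; adjusted p = 0.0391, and 0.474 with an estimated correlation), a call that ended without 48 h replicate 2 (0.0533) and within the high class (0.0610). Counts adjusted over the list alone were the same for the other lists called.

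The comparison of 72 h with 0 h covers the whole induction. Higher genes numbered 7419 and lower genes 6671, of which 3319 and 2942 changed at least 2-fold. With the class as a term 7552 were higher and 6646 lower, and within the low class (3 libraries against 2) 8283 and 7937, with none opposite. Pan-neural genes rose (17 rose and 1 fell of 18; adjusted p = 7.2e-09, and 0.0175 with an estimated correlation). PAX6 (chromosome 11, 31806327 to 31839509) went from 0.678 ± 0.165 to 95.8 ± 3.86 CPM (7.12 ± 0.20), SOX1 stood at 8.87 ± 0.17, and the neural cadherin gene CDH2 at 2.78 ± 0.08. DLK1, a Notch ligand-like gene (chromosome 14, 101192042 to 101204561), reached 493 ± 18.4 CPM (9.73 ± 0.18). FABP7, a fatty acid carrier of radial glia, was the 1 that fell (-2.95 ± 0.11). LMX1A, a LIM homeobox factor of the roof plate and midbrain (chromosome 1, 165171104 to 165325952), went from 0.0126 ± 0.00744 to 27.4 ± 0.670 CPM (10.97 ± 0.20). WNT1, a ligand of the midbrain and dorsal midline, had 2204 counts against 1 at 0 h, a ratio of 1988 (counting interval 356 to 78563). EMX2, a forebrain homeobox gene, had 2672 counts against 2, a ratio of 1205 (333 to 9957). BARHL1 (9.71 ± 0.22), LMO1 (9.92 ± 0.25) and LIX1 (9.46 ± 0.19) rose as well. Anterior neural factors rose (9 rose and 2 fell of 13, adjusted p = 0.00192, and 0.0388 with an estimated correlation), with LHX5 at 8.57 ± 0.15, OTX1 at 5.87 ± 0.27 and RAX, an eye field factor, at 4.65 ± 0.17. Posterior neural factors did not pass at 48 h (3 rose and 2 fell of 10, adjusted p = 0.867) or 72 h (6 rose and 2 fell, adjusted p = 0.310). Among them PAX2 had 732 counts at 72 h against 1 at 0 h, a ratio of 660 (counting interval 118 to 26116). WNT targets rose (8 rose and 1 fell of 12, 8 and 2 adjusted over the list alone; adjusted p = 0.00557, and 0.0435 with an estimated correlation), with SP5 (chromosome 2, 171571847 to 171574588) at 10.57 ± 0.28 and the antagonist gene DKK1 at 5.55 ± 0.19.

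Pluripotency factors had their lowest list median at 72 h (-1.83; 2 rose and 13 fell of 15; adjusted p = 1.3e-06, and 0.0175 with an estimated correlation). NANOG fell from 138 ± 6.61 to 0.504 ± 0.0818 CPM (-8.09 ± 0.12, adjusted p = 2.1e-21), TDGF1 changed by -6.15 ± 0.11, and POU5F1, uncertain as above, by -3.38 ± 0.14. LIN28A (0.53 ± 0.08) and SALL4 (1.09 ± 0.09) were the members that rose. Activin/Nodal/TGF-beta targets (1 rose and 10 fell of 11; adjusted p = 8.4e-05, and 0.0175 with an estimated correlation) and FGF/ERK genes (12 of 14 fell; adjusted p = 1.3e-06, and 0.0255 with an estimated correlation) were low, with ETV4 at -5.63 ± 0.12. All 10 epithelial genes fell (adjusted p = 1.8e-05, and 0.0435 with an estimated correlation), with EPCAM, an adhesion molecule (chromosome 2, 47572297 to 47614740), at -2.72 ± 0.13 and the E-cadherin gene CDH1 at -0.93 ± 0.06. Of 21 cholesterol synthesis genes 20 fell (adjusted p = 9.4e-12, and 0.0469 with an estimated correlation). The stress response list (2 rose and 11 fell of 14; adjusted p = 9.2e-04, and 0.0696 with an estimated correlation) and all 6 metallothionein genes (adjusted p = 2.3e-04, and 0.179 with an estimated correlation) fell. Immediate-early genes fell (3 rose and 11 fell of 15; adjusted p = 0.0251, and 0.416 with an estimated correlation), with FOS at -3.60 ± 0.12, though not without 0 h replicate 3 (0.0501). Outside the lists, METTL7A (-7.27 ± 0.15) and the phospholipase gene PLA2G3 (-6.77 ± 0.13) fell, and TMEM26 had 2 counts against 2780 at 0 h, lower by a ratio of 1541 (426 to 12730). Counts adjusted over the list alone were the same for the other 10 lists called. Counting intervals and floors cover counting error only.

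**Figure D3:**
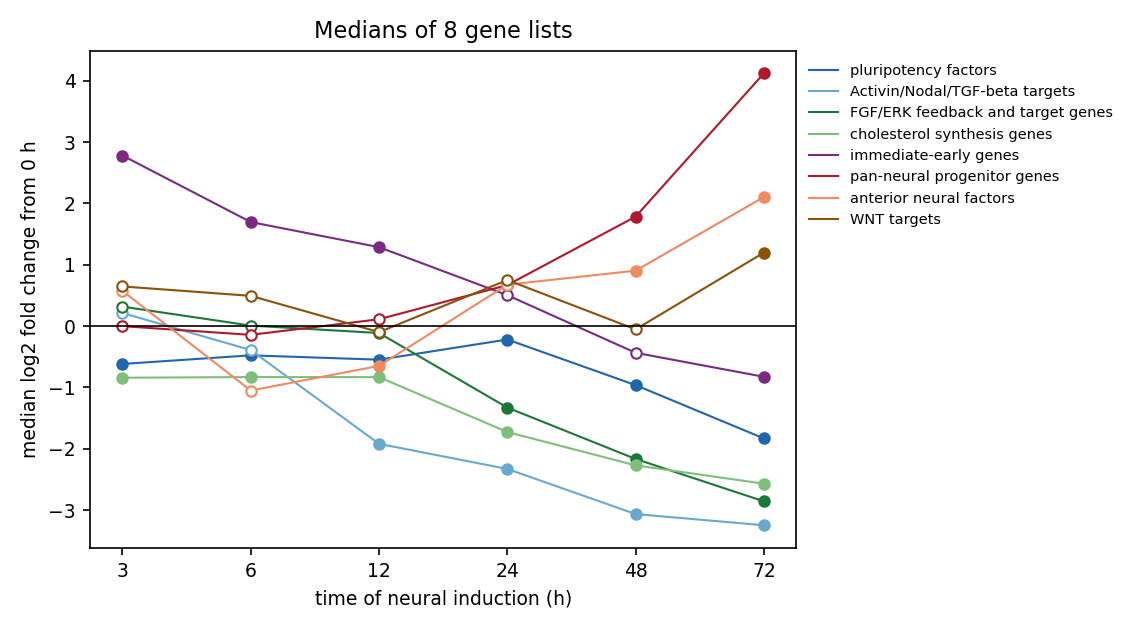
Median log2 fold change from 0 h of 8 gene lists at each later time point. Filled points have adjusted p under 0.05 with the preset correlation. The cholesterol list fell from -0.84 at 3 h to -2.57 at 72 h, and the pan-neural list reached 4.12.

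**Figure D4:**
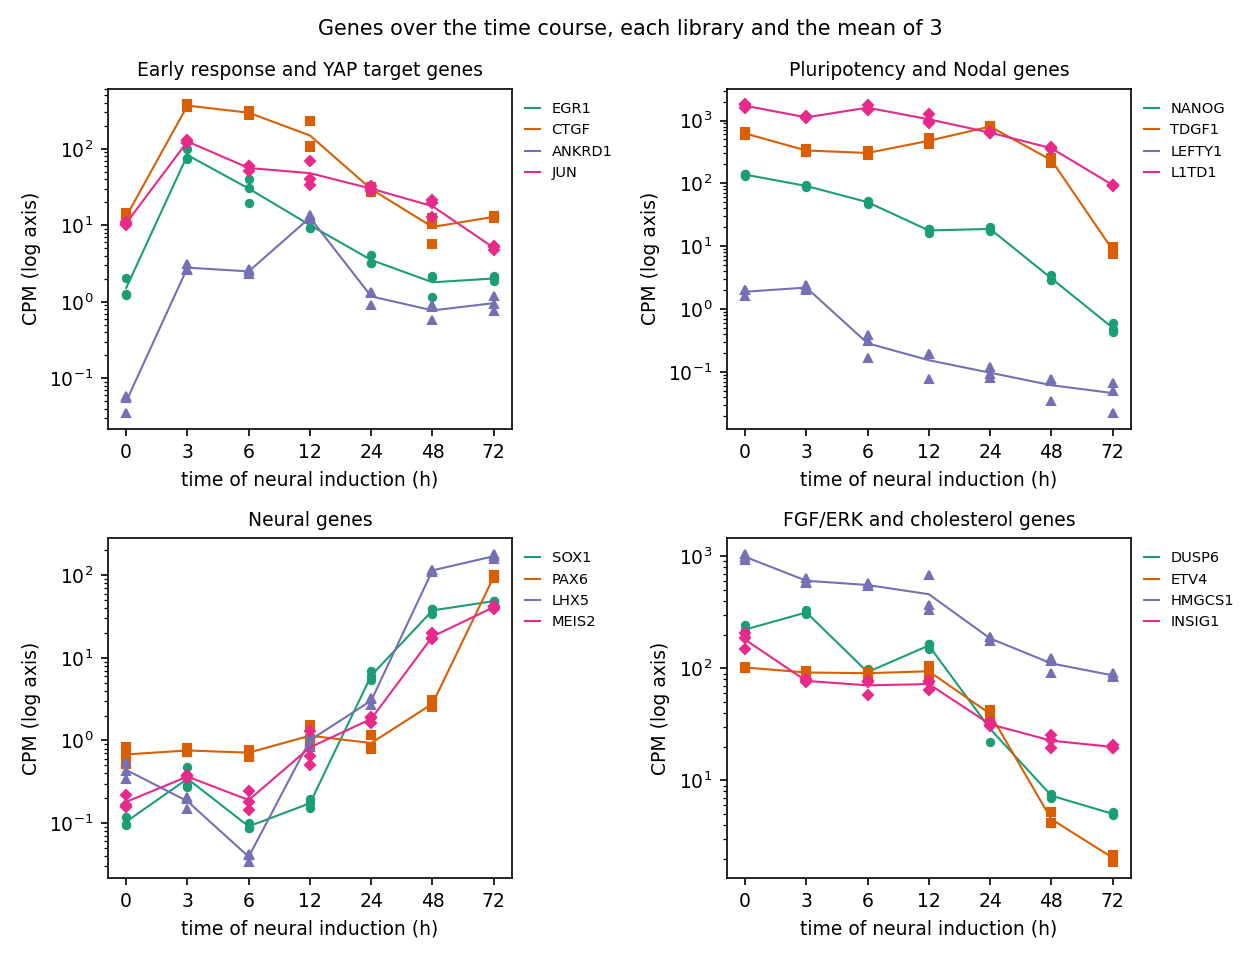
Level in CPM (log axis) of named genes in each library (points) and the mean of 3 (lines) over the 7 time points. EGR1 was highest at 3 h (82.9 CPM), NANOG fell to 0.504 CPM at 72 h, and PAX6 rose to 95.8 CPM.

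Lists of other cell fates did not pass at any time point, with the exception of endoderm markers at 12 h. Neural crest markers (9 measured) showed single members that moved, with FOXD3 at -8.05 ± 0.20 and SOX10 at 3.41 ± 0.18 at 72 h, and a list test of adjusted p = 0.682. Neuron markers (6 rose and 5 fell of 13 at 72 h; adjusted p = 0.954) included TUBB3, a neuronal tubulin that fell (-1.13 ± 0.10), and STMN2, which rose (1.86 ± 0.26). Surface ectoderm, amnion and trophoblast markers were closest to passing at 3 h (8 rose and 2 fell of 11; adjusted p = 0.0922), and at 72 h 5 members rose and 5 fell, with a median of 0.32 and a test pointing down (adjusted p = 0.945). Primitive streak markers (7 rose and 3 fell of 10 at 72 h; adjusted p = 0.145) included GSC, an organizer factor, at 3.29 ± 0.112 CPM (6.82 ± 0.21) and the ligand gene WNT8A (5.34 ± 0.28). Mesoderm, cardiac and endothelial markers (5 rose and 2 fell of 9; adjusted p = 0.819) included KDR, a VEGF receptor gene that fell (-2.13 ± 0.11). Fibroblast markers came closest at 12 h (4 rose and 1 fell of 8; adjusted p = 0.0615), and passed without 0 h replicate 3 (0.0340) or 12 h replicate 3 (0.0395). Naive pluripotency markers (5 rose and 1 fell of 9 at 3 h; adjusted p = 0.152) included KLF5 (3.95 ± 0.15). Heat shock genes (0 rose and 3 fell of 9 at 12 h; adjusted p = 0.0792) and ribosomal protein genes (12 rose and 0 fell of 20 at 72 h; adjusted p = 0.0577) did not pass either. The heat shock list passed without 12 h replicate 3 (0.0175) and with no filter on low counts (0.0350). The ribosomal list passed without 0 h replicate 1 (0.0322) or 12 h replicate 3 (0.0453), within the low class (0.0126), with the replicate number as a block (0.0441) and with no filter (0.0423). At 3 h that list pointed down (0 rose and 5 fell, 0 and 1 adjusted over the list alone; adjusted p = 0.152), and passed there with the class as a term (0.0445), within the low class (0.00437), with no filter (0.0486) and without 0 h replicate 3 (0.0460). BMP targets had their smallest adjusted p at 6 h (0.0713), and passed there only without the filter on low counts (0.0333). Adjusted over the list alone, counts at these time points were the same, except that neuron markers had 7 higher and ribosomal genes at 3 h had 1 lower.

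Comparisons of successive time points asked in which interval genes changed. From 3 to 6 h 4527 genes rose and 6207 fell, and from 6 to 12 h 5351 rose and 5620 fell. With the class as a term these were 4477 and 5641, then 5654 and 5785. Within the low class 5930 rose and 6389 fell from 3 to 6 h (1 library against 3), with 1 gene opposite, and within the high class 4204 rose and 3347 fell from 6 to 12 h (3 against 2). From 12 to 24 h 6582 rose and 5414 fell, from 24 to 48 h 4361 and 4773, and from 48 to 72 h 4416 and 4849. The class as a term gave 5408 and 4710, then 3029 and 3284, then 3077 and 3900, all with no gene opposite. Of the genes called without the term, 4775 and 4129 remained in the first of these intervals, 2460 and 2936 in the second, and 2512 and 3316 in the third. SMAD7 fell between 3 and 6 h (-2.85 ± 0.08). LHX5 rose between 6 and 12 h (4.65 ± 0.21), when OTX2 came back up (2.80 ± 0.11). The LHX5 level was low then, 0.0335 to 0.0428 CPM in the 6 h libraries and 0.843 to 1.18 at 12 h. Its larger gain in CPM came between 24 h (2.67 to 3.30) and 48 h (110 to 117). SOX1 rose most between 12 and 24 h (5.14 ± 0.16). LMX1A (8.28 ± 0.23), FEZF1 (3.90 ± 0.09) and CYP26A1 (4.67 ± 0.12) rose between 24 and 48 h. PAX6 (5.11 ± 0.18) and SP5 (5.27 ± 0.18) rose most, and TDGF1 fell most (-4.74 ± 0.11), between 48 and 72 h. NANOG fell in all intervals but that from 12 to 24 h, where it did not pass (0.08 ± 0.09, adjusted p = 0.452).

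A last test asked which genes went above or below both ends of the course. Of 21719 genes, 6445 were transiently higher and 4583 transiently lower, 3360 and 1108 of them by at least 2-fold against both 0 and 72 h. The class as a term gave 6364 and 4524. The test was not run within a class, and all libraries of 12 and 48 h differ in class from those of 72 h. Among the genes changed 2-fold, the turning point was at 3 h for 1699 higher and 192 lower ones, at 6 h for 479 and 610, at 12 h for 417 and 143, at 24 h for 390 and 71, and at 48 h for 375 and 92. IL8 at 6 h was at least 4734-fold above 0 h and at least 5248-fold above 72 h, where it had no counts. Its level was 35.7 CPM. TNFRSF9, a costimulatory receptor gene, peaked at 12 h at 13.1 CPM, and the smaller of its log2 changes against the ends was 8.38. CH25H, which makes an oxysterol from cholesterol, reached 20.03 ± 4.43 CPM at 12 h (7.15). VGF reached its peak at 12 h (6.13), as did the connexin gene GJB2 (5.94). Of the 10 genes with the deepest dip, KCNH5 was lowest at 48 h and the others at 6 h. IRX1, an Iroquois homeobox gene (chromosome 5, 3595946 to 3601517), went from 1.45 CPM at 0 h to 0.0652 at 6 h and 164 at 72 h, and CRB2 from 23.7 to 1.48 and 182. The cadherin gene CDH9 (2.96, 0.199 and 18.7 CPM) followed the same course. In simulated data, where changed genes had at least 1 CPM at 0 h, this test found 78% of genes raised 2-fold at 12 h alone. It found 72% of genes lowered 2-fold there, and called 0 of 19996 other genes. Few genes were changed in those data, so these rates do not cover a course in which most genes change.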

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

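No called list and no named gene changed direction under any alternative run. Among all genes, 1 called at 24 h against 0 h and 1 called from 3 to 6 h went the opposite way within the low-share libraries. Whether more genes were higher or lower held under all settings run at 3 and 24 h against 0 h, from 3 to 6 h and from 48 to 72 h, and for transient genes and the numbers changed at least 2-fold. In the other contrasts it turned under some setting and is not a stable feature. DESeq2 size factors turned it from 6 to 12 h (5730 higher and 5223 lower), from 12 to 24 h (5883 and 6149) and at 72 h (6989 and 7108), no filter at 6 h (5968 and 6063), and a fit to only the libraries compared at 12 h (3146 and 2660) and from 24 to 48 h (4892 and 4585). Without 12 h replicate 3, genes higher at 48 h than at 0 h (7197) were fewer than lower ones (7243). The class of mitochondrial rRNA share turned it as well. As a term it did so at 12 h (4538 higher and 4331 lower), and the high-share libraries did from 6 to 12 h (4204 and 3347). Fits within a class that leave 1 library in a group turned it at 6 h in both classes and at 12 h in the high class. The number of genes called stayed within 1.5 times the value given in all 11 contrasts, the course test and the transient tests with DESeq2 size factors, DESeq2, no filter, the replicate block, no robust estimation, without the 10 most abundant and mitochondrial genes, the class of mitochondrial rRNA share as a term, the low-share libraries (where a contrast has some on both sides) and the highest entry per name. The last 3 settings and the high-share libraries were chosen after seeing the data. The stricter filter tested fewer genes, which lowers counts by construction. It called 11658 genes over the course, and 3945 higher and 3583 lower at 3 h (996 and 368 by at least 2-fold), 3974 and 3694 at 6 h (757 and 688), 626 and 323 by at least 2-fold at 12 h, 4097 and 3389 at 24 h (983 and 331), 4576 and 3978 at 48 h (1311 and 762), and 4631 and 4181 at 72 h (1410 and 1237). It called 2667 higher and 3506 lower from 3 to 6 h, 4259 higher from 12 to 24 h, 2939 lower from 24 to 48 h, 2795 higher and 3025 lower from 48 to 72 h, and 3447 transiently higher and 3051 transiently lower genes. A fit to only the libraries compared called 2660 genes lower at 12 h than at 0 h and 3188 lower at 12 h than at 6 h. The high-share libraries, of which there are fewer, called 2955 higher and 3116 lower at 6 h, 2424 and 1859 at 12 h, 4367 and 3720 at 48 h, and 3347 lower from 6 to 12 h. Without 1 library, genes at least 2-fold lower at 12 h ranged from 701 to 1428, for which the cause was not tested, genes changed over the course from 20271 to 21163, list calls from 65 to 70 and named genes past the threshold from 363 to 365.

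List calls numbered 24 with an estimated correlation against 67 with the preset one, a difference that lies in the correlation itself. They numbered 67 with DESeq2 size factors, 76 with no filter, 67 with a prior count of 0.5 and 64 with the rRNA class as a term. Of 365 named calls, 364 passed with DESeq2 and 364 with the class as a term. Within the high-share libraries, which are fewer, 55 of 59 passed at 6 h, 44 of 48 at 12 h and 48 of 49 at 48 h. Those lost included CYR61 (adjusted p = 0.138 at 6 h), LDHA (0.130 at 6 h), TERF1 (0.0889 at 12 h), UHRF1 (0.180 at 12 h) and RRM2 (0.139 at 48 h). The replicate number as a block gave 7476 higher and 6702 lower genes at 72 h and 68 list calls. Of 63 pairs of libraries with the same number at different time points, 10 had a residual correlation over 0.1 (range -0.206 to 0.436), and 13 of 21 libraries correlated best with a library of their own number. The median was 0.0107 for pairs of the same number and -0.0170 for other pairs. All 10 pairs were also of the same rRNA class, so number and class are not told apart there. Some dependence between libraries, which the model takes as independent, stays open. Scaling with DESeq2 size factors moved the median change of all genes by at most -0.0649 on the log2 scale. At totals of 73689263 to 314729551 counts, depth limits mainly genes at or near 0. Genes with a group at 0 made up 0.781% to 1.56% of the genes changed at least 2-fold, and a group with 1 to 3 counts was found in another 148 of 5250 such genes at 3 h and 238 of 6261 at 72 h. Counting such genes at their bounds moved 0 of 198 list medians by over 0.1.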

Other observations

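The added gene lists, the thinning of the libraries to 1 total and the settings by rRNA share in this part were chosen after their results or the data had been seen. The other tests were written down before their results were seen. WNT ligand genes rose as a list at all later time points but 6 h (adjusted p = 0.406). Of 19 measured, 12 rose and 2 fell at 3 h (adjusted p = 0.00775, and 0.0281 with an estimated correlation), 12 rose and 1 fell at 12 h (adjusted p = 1.4e-05, and 0.00211 with an estimated correlation) and 13 rose and 2 fell at 24 h (adjusted p = 9.7e-05, and 0.00473 with an estimated correlation). Then 14 rose and 4 fell at 48 h (adjusted p = 3.5e-04, and 0.00786 with an estimated correlation), and 16 rose and 2 fell at 72 h (adjusted p = 1.4e-05, and 0.00211 with an estimated correlation), with the same counts adjusted over the list alone except for 13 that rose at 3 h. Only 1 of the ligand genes was over 1 CPM at 0 h, and weakly expressed genes rose as a class at 3 h, so the 3 h call is not set apart from that rise, and no comparison with lists of like expression was run. From 12 to 72 h the genes of lower level at 0 h had medians of 0.14 to 0.29, against 1.32 to 2.46 for the ligands. WNT10A, WNT10B and WNT1 were among the largest rises at 48 or 72 h, so the list is not independent of these results. Their summed level went from 8.74 ± 0.343 CPM at 0 h to 136 ± 5.08 at 48 h and 77.1 ± 5.25 at 72 h (SD, n = 3). WNT4 alone reached 51.9 ± 3.11 CPM at 48 h. Of 9 Frizzled receptor genes 5 fell and 4 rose at 3 and at 6 h, and the list did not pass (adjusted p = 0.406 at both). Their summed level went from 629 ± 40.5 CPM at 0 h to 365 ± 3.20 at 3 h. At 24 h the list passed with adjusted p = 0.0424, and 0.109 with an estimated correlation. At 48 h 8 rose (adjusted p = 1.6e-04, and 0.0112 with an estimated correlation). FZD5 went from 66.1 ± 4.34 CPM at 0 h to 27.8 ± 1.56 at 3 h and 254 ± 7.30 at 48 h. The 4 R-spondin genes did not pass as a list at 72 h (adjusted p = 0.0605), although RSPO2 reached 24.3 ± 1.46 CPM. Of 39 HOX genes, which mark the hindbrain and spinal cord, none had a mean of 1 CPM at any time point. Their summed level was 0.154 ± 0.0328 CPM at 0 h, 0.973 ± 0.0209 at 3 h and 0.0892 ± 0.0164 at 72 h.

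At 3 h, weakly expressed genes were higher as a class. The median log2 change of the 10860 genes of lower mean expression at 0 h was 0.71, against -0.25 in the genes above them. As 0 h is also the reference, such a split can by itself raise the lower genes. From 6 to 72 h the medians kept these signs but were smaller, 0.14 to 0.29 and -0.09 to -0.05. Olfactory receptor genes have no known use in these cells. Their sum, on unscaled totals, went from 2.95 ± 0.156 CPM at 0 h to 9.51 ± 0.797 at 3 h. Scaling factors of 1.16 to 1.21 at 3 h against 0.910 to 1.02 at 0 h make that rise smaller. Genomic DNA in the 3 h libraries would fall on all genes alike, but the gain per exonic kb was larger in 1376 silent genes within 50 kb of an expressed gene than in 346 silent genes over 500 kb away, by a ratio of 3.43, 3.28 and 2.75 in the 3 libraries. These sets differed at 0 h too, with 0.00601 CPM per kb near and 0.00154 far. Silent genes here include those listed at 0 in all libraries, which may not be silent. If DNA is counted alike in both sets, the ratio argues against DNA as the whole cause. A smaller part, or a difference in counting between the sets, stays open. Among the low-share libraries the median was 0.72, which argues against the rRNA class, and with all libraries thinned to 73689263 counts the lowest 3 h library still had 1786 more genes with a count than the highest 0 h library, which argues against depth. The share of the nuclear RNAs MALAT1 and NEAT1 was also higher, 0.313 ± 0.0508% of counts against 0.0935 ± 0.0519% at 0 h, but it was 0.415 ± 0.0466% at 72 h, and a larger share of nuclear RNA at 3 h was not tested as a cause and stays open. The posterior neural list rose beyond this class effect, with a median of 2.71 against 1.13 in random lists of like expression (percentile 99.93 of 10000 lists), so its rise may be partly its own, while a response to the medium or its change at 0 h stays open and untested.

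Between 12 and 72 h, 965 of the 3564 genes called in all 3 steps went up, down and up or the reverse, in step with the high and low rRNA share of the time points. A library batch could give this. The number of genes that would alternate without a batch was not computed, so the count by itself does not point to a batch. The batch effect estimated from the 0 and 6 h libraries had the sign it needs in 57.2% of these genes (95% interval 54.01 to 60.35). Among the other genes that effect was below 0 in 50.9%. The interval counts genes as independent, though all of them share 1 estimate from the same few libraries, so it is too narrow. The prediction against a batch was at most 60%, and the interval passes that bound, so the test leaves the batch open. With the class as a term 413 genes still alternated. The median size of the estimated batch effect was 0.145 on the log2 scale, against 0.709 for the steps. The share is confounded with the time point in these steps, so batch and time cannot be told apart for these genes.

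Cholesterol synthesis genes were lower as a list at 24, 48 and 72 h, to a median log2 change of -2.57 at 72 h. The list passed also at 3, 6 and 12 h, but not with an estimated correlation (adjusted p = 0.129, 0.0781 and 0.0637). Among the low-share libraries the median was -2.63, which argues against the rRNA class as the cause. An excess of sterol, for instance from a changed medium, might give such a fall, and would also raise LXR targets and lower fatty acid synthesis genes. At 24 h, 7 of 9 fatty acid synthesis genes fell (adjusted p = 6.7e-05, and 0.0675 with an estimated correlation). The 6 LXR targets had a median change of 0.28, with 3 that rose, among them ABCA1 (1.93 ± 0.08), and 1 that fell, so that test did not decide. At the other time points their median was -0.50 at 3 h, -0.42 at 6 h, -0.14 at 12 h, -0.09 at 48 h and -0.69 at 72 h, and they passed as lower at 6 h (adjusted p = 0.0424, and 0.109 with an estimated correlation). ABCA1 rose also at 48 h (2.69 ± 0.08) and 72 h (1.77 ± 0.08), and the summed level of the targets went from 86.9 ± 4.02 CPM at 0 h to 189 ± 8.46 at 24 h, 249 ± 10.6 at 48 h and 132 ± 1.59 at 72 h. That sum mainly follows ABCA1, which alone held 31.0 CPM of it at 0 h, 118 at 24 h, 200 at 48 h and 106 at 72 h. Of the 6 targets, 2 rose and 1 fell at 48 h, and 1 rose and 3 fell at 72 h. Members moved both ways, and sterol excess is left open.

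Other ways to split the 6 libraries of a contrast were counted, with 10 splits each, which are too few for a share under 0.05. In each of the 11 contrasts 1 split, the real one, gave as many genes. From 3 to 72 h against 0 h the real splits called 14095, 12126, 9517, 11691, 13545 and 14090 genes and the highest other split 0, 359, 845, 0, 0 and 1. The split with 359 genes at 6 h set apart the low-share from the high-share libraries. The successive steps called 10734, 10971, 11996, 9134 and 9265 genes against 0, 5, 0, 0 and 0. Of 100 assignments of the 21 libraries to the time points, 1, the real one, gave as many changed genes (20432, highest other 847). The same held for transiently higher genes (6445, highest other 4) and transiently lower genes (4583, highest other 160). Other splits and assignments mix time points, so differences between time points add to the spread and lower the calls. The assignments speak against a random allotment of libraries to time points. They do not bear on libraries that share a culture or a batch.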
